A study of Homo sapiens and Rattus norvegicus with 106 samples.

How the data were processed

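Gene expression was measured on Affymetrix oligonucleotide arrays in uterine leiomyoma, the benign smooth muscle tumour also called a fibroid, and in myometrium, the muscle layer of the uterus. The human part held 77 arrays, 50 of leiomyoma and 27 of myometrium, from 23 donors with 1 to 3 biopsies per tissue, and 22 donors gave both tissues. The rat part held 29 arrays of the Eker model, 14 of leiomyoma and 15 of myometrium, each with a donor number that occurred once. The labels name all rat tissue, leiomyoma and myometrium, as Eker rat tissue, but do not give the genotype of each animal. The Eker model rests on a germline defect in 1 copy of Tsc2, which encodes tuberin, an inhibitor of the mTOR complex 1 kinase.

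The values analysed were linear intensity values per probe set, as deposited by the authors in 1 table per species. The software and the normalization behind them were not given in the sources used here. After trimming 2% of the values from each end, the mean of every array lay between 99.95 and 99.97, so each array had the same trimmed mean. No pair of arrays held identical values. The human table had 54675 probe sets, of which 62 were controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none in the platform annotation provided. The rat table had 31099 probe sets, with 57 controls, 20826 with 1 gene symbol, 436 with several and 9780 with none. Symbols followed the platform annotation, updated through Entrez numbers or unique synonyms where a table allowed. Probe sets with several symbols or none were never named, and no genome coordinates were used. Arrays give no read depth, so their number and the signal over background limit the precision.

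An offset equal to the 20th percentile of all values of a table was added before taking log2. It was 5.45 for human and 12.0 for rat, and it understates the fold change of dim genes. Probe sets whose mean log2 value lay above the 40th percentile were kept, controls were left out, and the brightest probe set stood for its gene. This left 14203 human and 10481 rat genes. Among genes with several probe sets, 4 of 6930 human genes and 124 of 2768 rat genes had probe sets called in opposite directions. XIST, TSIX and Y-linked genes were left out everywhere.

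Human arrays of the same donor and tissue were averaged on the log2 scale, giving 23 leiomyoma and 22 myometrium means, because biopsies of a donor are not independent. Leiomyoma was compared with myometrium within each species by limma (lmFit and eBayes, two-sided), without a donor block. Adjusted p is the Benjamini-Hochberg value over the genes tested, and a gene was called higher or lower at an adjusted p under 0.05. Errors given with log2 fold changes are standard errors. The labels give the donor of each human array, so human samples are paired. The deviations of leiomyoma and myometrium from their group means had a median correlation of 0.275 within donors, over 0.1 in 19 of 22 donors and 0.043 at the lowest, against -0.016 between donors. Fits with the donor as a replicate block were therefore run as alternatives. No rat arrays could be paired by their donor numbers, and whether any came from the same animal is not known.

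The species were fitted separately, since their arrays differ in platform. Genes were matched by symbol ignoring case or by a unique synonym, which gave 8931 genes measured in both. Overlaps of calls were compared with the number expected for independent lists and by Fisher's exact test. The difference of the human and rat log2 fold changes was divided by its standard error, tested two-sided and adjusted over these genes. Arrays of different platforms compress fold changes to different degrees, so a difference in size alone can arise from the platform. The correlation of fold changes and the overlaps were set against 100 permutations of the rat labels each, the overlaps with the human calls kept and as many rat genes taken from each end of the ranking by moderated t as the real fit called.

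A set of 30 gene lists was fixed before the data were examined, together with the tests, the named-gene rule and 17 alternatives. They covered the mTOR pathway components, the mTORC1 and ATF4 amino acid and serine program, glycolysis and HIF targets, sterol and fatty acid synthesis, the insulin-like growth factor axis, cell cycle, collagens, other matrix genes, contractile genes, steroid receptors and targets, the TGF-beta, Wnt and retinoid pathways, leiomyoma driver loci, immediate early genes, interferon response, cytosolic ribosomal proteins and housekeeping genes. Marker lists covered epithelial, endothelial, lymphatic, fibroblast, lymphocyte, macrophage and myeloid, mast, adipocyte, mesothelial, nerve and glial, skeletal muscle and red blood cells. Lists with at least 5 measured members were tested with camera, 28 in human and 27 in rat, at a preset correlation of 0.01 and again with the correlation estimated from the arrays. Results of fry were also computed. A further pair of lists, of melanocytic and of lysosome genes, was written after single rat genes had been seen.

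Named genes were the 10 largest rises and 10 largest falls of each species among called genes, and up to 2 called members of each list in each direction. A fixed set of mTOR, growth factor, hormone receptor and matrix genes was added. Across species the rule took the 8 genes with the largest smaller moderated t in each shared direction and 5 in each opposed direction. Other genes are said to be chosen after their values were seen.

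The procedure was tested on simulated data made from the real means and spreads. For human, 62 of 100 genes changed by 0.5 log2 and 96 of 100 changed by 1 were recovered, with 7 false calls among 14203 genes. For rat, 77 of 100 and 100 of 100 were recovered with 11 false calls among 10481. The difference test recovered 184 of 200 genes changed by 1 with 8 false calls among 8931, and the list test found the 1 changed list in each species. The simulated genes were independent of each other and few were changed, so the list test was not tried on correlated genes. The estimated correlation within the real rat contractile list was 0.557.

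Alternatives changed the offset, the scaling between arrays, the filter, the choice of probe set, the averaging of biopsies, the donor block, the number of human samples, the test, a minimum fold and the matching of symbols. A further 4 alternatives were chosen after seeing the data. These left out arrays that correlated poorly with their group or took the median signal of the array, the mean of the epithelial markers, or the donor block together with the array median into the fit. Array quality measures were compared by two-sided permutation tests with 100000 resamples, which ignored the donor pairs of the human samples. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.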

Results

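The data compared leiomyoma with myometrium in human tissue and in the Eker rat, with the mTOR pathway as a stated interest of the series. Each array was scaled to the same trimmed mean. The median signal of an array was 26.7 ± 4.43 (SD, n = 23) in human leiomyoma and 28.4 ± 5.03 (SD, n = 22) in human myometrium, a difference within the spread (permutation p = 0.222). In rat it was 43.5 ± 2.13 (SD, n = 14) in leiomyoma against 48.2 ± 2.03 (SD, n = 15) in myometrium (permutation p = 1e-05, the smallest that the resamples can give, and adjusted p = 6e-05 over 6 measures). The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 0.51 ± 0.24 log2 in human leiomyoma and 0.58 ± 0.31 in human myometrium (SD; permutation p = 0.38), and 0.62 ± 0.16 against 0.70 ± 0.17 in rat (SD; permutation p = 0.215). The human tests of array median and actin ratio ignored the donor pairs, so a difference within donors is not excluded.

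Human leiomyoma expressed DCX, CAPN6 and GRIA2 at far higher levels than myometrium, part of the cell cycle and collagen genes at higher levels, and immediate early, epithelial, vascular, lymphocyte and mast cell genes at lower levels. The calls of the fixed lists behind this were lost with an estimated correlation between genes (lowest adjusted p = 0.0798). By fry in 1 direction these lists passed, with an adjusted p up to 0.0013 for the collagens, and the housekeeping list did not (adjusted p = 0.775). The largest rise was in DCX, which encodes a microtubule-binding protein of migrating neurons. It rose by 3.56 ± 0.47 log2, or 11.8-fold, from a mean intensity of 22.5 to 324, and was higher in 20 of 22 donors with both tissues (adjusted p = 3.1e-07). CAPN6, a calpain family member, rose by 3.48 ± 0.45 and GRIA2, a subunit of AMPA-type glutamate receptors, by 3.03 ± 0.39. The other large rises were ASB5 (3.25), the cytokine gene IL17B (2.82), CEMIP (2.73), the tryptophan dioxygenase gene TDO2 (2.31), MMP11 (2.3), the cardiac actin gene ACTC1 (2.29) and ADAM12 (2.15), each with an adjusted p of 7.9e-05 or less. The largest fall was in KRT19, a keratin of epithelia, at -2.71 ± 0.42 (intensity 16 against 136, higher in 0 of 22 donors). It was followed by ADH1B (-2.70), FOS (-2.68), FOSB (-2.56), ALDH1A1 (-2.55), ABCA8 (-2.38), CCN5 (-2.35), DPT (-2.32), MGST1 (-1.87) and NEGR1 (-1.83).

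In all, 1193 human genes were higher and 1645 lower in leiomyoma among 14203, or 20.0% of them, and 148 and 158 of these changed at least 2-fold. Of the called genes 42.0% were higher, and centring each array on its median moved this split to 59.9% with 930 genes lower. With the donor as a random block over all 77 arrays 2066 genes were higher, with only the first biopsy of each donor and tissue 693 were higher, and with the epithelial marker mean as a covariate 425 were higher and 614 lower.

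Part of the cell cycle and collagen genes rose in human leiomyoma. In the cell cycle list 16 of 33 measured genes rose and 1 fell, or 20 and 1 adjusted over the list alone, with the thymidylate synthase gene TYMS at 1.74 ± 0.25, the cyclin gene CCND1 at 1.08 ± 0.23 and the inhibitor gene CDKN1B at -0.40 ± 0.11. The list shifted up by camera (adjusted p = 3.5e-08), though the call was lost at adjusted p = 0.0941 with an estimated correlation. MKI67, a marker of dividing cells, was at 0.09 ± 0.15 (adjusted p = 0.76). Collagen genes rose in 11 of 24 cases and fell in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 6.5e-05; adjusted p = 0.152 with an estimated correlation). COL11A1 rose by 0.91 ± 0.26, COL5A2 by 0.82 ± 0.13, COL1A1 by 0.45 ± 0.14 and COL3A1 by 0.26 ± 0.08, whereas COL14A1 fell by 0.67 ± 0.16. With only the first biopsy the calls of COL1A1, COL3A1 and COL11A1 were lost (adjusted p = 0.150, 0.167 and 0.0764), as they were with 14 against 14 donor means, where CDKN1B, COL14A1 and TGFB3 were not called either (adjusted p from 0.0547 to 0.214). Median centring ended that of CDKN1B (adjusted p = 0.0989). With the epithelial marker mean as a covariate the calls of 7 of these genes were lost (adjusted p from 0.0603 to 0.189). Standard errors widened, while COL1A1 (0.51 ± 0.19), COL3A1 (0.28 ± 0.11), CDKN1B (-0.42 ± 0.15) and TGFB3 (0.95 ± 0.32) kept their size within the error. The changes of COL14A1 (-0.54 ± 0.21), CCND1 (0.67 ± 0.30) and TGFB2 (0.71 ± 0.28) were smaller as well. Of 34 other matrix genes 9 rose, among them MMP11 and ADAM12, and 4 fell, among them DPT and FBLN1 (-1.06 ± 0.17), or 10 and 4 adjusted over the list alone. That list missed the threshold (camera adjusted p = 0.0503; adjusted p = 0.563 with an estimated correlation) but passed it with the donor as a random block (adjusted p = 0.038) and with no filter (adjusted p = 0.0255). TGFB3, a growth factor that induces matrix, rose by 1.1 ± 0.24 and TGFB2 by 1.11 ± 0.22.

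Immediate early genes, which respond within minutes to stimuli, were lower in human leiomyoma. Of 23 measured members 17 fell and 0 rose, or 20 and 0 adjusted over the list alone, led by FOS at -2.68 ± 0.50 and FOSB at -2.56 ± 0.62 (camera adjusted p = 1.8e-11; adjusted p = 0.122 with an estimated correlation). Interferon response genes fell in 9 of 16 cases (camera adjusted p = 1.1e-04; adjusted p = 0.143 with an estimated correlation), with IFI44 at -0.76 ± 0.13 and BST2 at -0.79 ± 0.19. The count was also 9 adjusted over the list alone.

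Markers of other cell types moved with the human groups. Endothelial markers fell in 12 of 16 cases (13 adjusted over the list alone), with the endomucin gene EMCN at -0.89 ± 0.13 and the VEGF receptor gene KDR at -0.79 ± 0.15 (camera adjusted p = 6.1e-08; adjusted p = 0.122 with an estimated correlation). Lymphatic markers fell in 4 of 6 (camera adjusted p = 0.0065; adjusted p = 0.0798 with an estimated correlation), with LYVE1 at -1.25 ± 0.23. Mast cell markers fell in 6 of 7, including the tryptase gene TPSAB1 at -1.55 ± 0.31 and CPA3 at -1.54 ± 0.26 (camera adjusted p = 1.05e-06; adjusted p = 0.0798 with an estimated correlation). Lymphocyte markers fell in 7 of 12 (IL7R, -0.96 ± 0.16; camera adjusted p = 5.8e-05; adjusted p = 0.0798 with an estimated correlation) and fibroblast markers in 8 of 12 (DPT, -2.32 ± 0.29; FBLN2, -1.54 ± 0.25; camera adjusted p = 8.0e-06; adjusted p = 0.0798 with an estimated correlation). Epithelial markers fell in 5 of 10, led by KRT19 and MMP7 at -1.31 ± 0.36 (camera adjusted p = 0.0045; adjusted p = 0.122 with an estimated correlation). Adjusted over the list alone, the lymphatic, mast, lymphocyte, fibroblast and epithelial falls numbered 4, 7, 8, 8 and 6. Without probe sets that can bind several transcripts the epithelial, fibroblast and lymphatic lists were not called (camera adjusted p = 0.236, 0.0843 and 0.0726), nor was the lymphatic list with the epithelial marker mean as a covariate (0.0525). MMP7 was not called with 14 against 14 donor means (-1.36, adjusted p = 0.0533). With the epithelial marker mean as a covariate the calls of BST2, KDR and MMP7 were lost (adjusted p = 0.0604, 0.0704 and 0.675). BST2 stayed at -0.77 ± 0.26 with a wider error, whereas KDR went to -0.57 ± 0.20 and MMP7 to -0.41 ± 0.44.

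No shift of the mTOR pathway components as a group was called in human leiomyoma. Of 40 measured members 5 rose and 4 fell, the same counts as adjusted over the list alone, with a median of 0.03. The camera adjusted p was 0.456, or 0.777 with an estimated correlation. Fry gave no shift in 1 direction (adjusted p = 0.614) but called changes either way (adjusted p = 1.7e-06). Fry tests a list without reference to other genes. The 9 of 40 members called were near the 20.0% of all human genes called, so these changes are not particular to the list. The insulin receptor substrate gene IRS1 rose by 0.69 ± 0.20 and the PI3-kinase subunit gene PIK3R1 by 0.64 ± 0.14, while DEPTOR, an inhibitor that binds mTOR, was at -0.99 ± 0.20 and the AMPK subunit gene PRKAA2 at -0.76 ± 0.13. The call of PIK3R1 was lost with 14 against 14 donor means (0.56, adjusted p = 0.0790). Those of IRS1, PIK3R1 and DEPTOR were lost with the epithelial marker mean as a covariate (adjusted p = 0.0604, 0.0947 and 0.107). IRS1 was then at 0.79 ± 0.27, so its call ended through a wider error, while PIK3R1 (0.50 ± 0.19) and DEPTOR (-0.70 ± 0.27) were also smaller. TSC2 was at 0.12 ± 0.20, TSC1 at -0.10 ± 0.07, RHEB at 0.08 ± 0.06, MTOR at 0.08 ± 0.08, RPTOR at 0.06 ± 0.24, RICTOR at -0.12 ± 0.08 and RPS6KB1 at -0.05 ± 0.06, none past the threshold (lowest adjusted p = 0.30). AKT1 at 0.29 ± 0.11 (adjusted p = 0.061) and EIF4EBP1 at 0.43 ± 0.18 (adjusted p = 0.091) missed the threshold too, but were called with the donor as a random block (adjusted p = 0.0027 and 0.0014), with array weights (0.0119 and 0.0365) and without the 5 human arrays that correlated poorly with their group (0.0092 and 0.0223). Of 25 genes of the mTORC1 and ATF4 amino acid and serine program 7 rose and 1 fell (9 and 2 adjusted over the list alone). They included the cystine transporter gene SLC7A11 at 0.74 ± 0.18 and the proline synthesis gene PYCR1 at 0.70 ± 0.13 (camera adjusted p = 0.0331; adjusted p = 0.193 with an estimated correlation). This call was lost in 6 of the fits fixed in advance. Among them were the donor as a fixed block (adjusted p = 0.058), quantile normalization (adjusted p = 0.0603) and the fit without probe sets that can bind several transcripts (adjusted p = 0.272). Glycolysis and HIF targets rose in 2 and fell in 4 of 27 cases, and sterol and fatty acid synthesis genes rose in 1 of 16 (camera adjusted p = 0.649 and 0.322), with counts unchanged adjusted over the list alone. The growth factor gene IGF1 was at -0.05 ± 0.20, IGF1R at 0.15 ± 0.09 and INSR at 0.09 ± 0.11, none called.

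Few contractile genes changed between the human tissues. Of 23 members 1 rose, MYOCD, the myocardin coactivator of the smooth muscle program, at 0.75 ± 0.15, and 1 fell, ITGA8 at -0.36 ± 0.12. The ITGA8 call was lost in 5 of the fits fixed in advance, among them the donor as a fixed block (adjusted p = 0.0572). Adjusted over the list alone 1 rose and 0 fell, and the list median was -0.03 (camera adjusted p = 0.649; adjusted p = 0.882 with an estimated correlation).

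**Figure D1:**
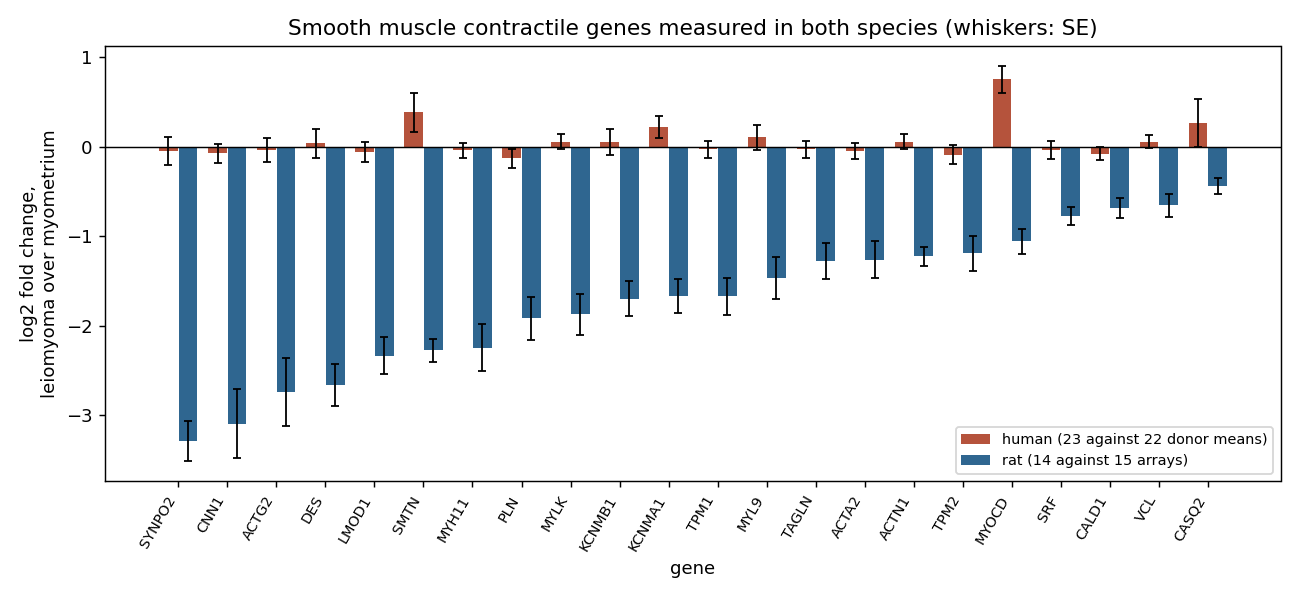
Log2 fold change of leiomyoma over myometrium (vertical axis) for the 22 contractile genes measured in both species, with bars for the fitted change (red, human, 23 against 22 donor means; blue, rat, 14 against 15 arrays) and whiskers for the standard error. All 22 rat bars lie below 0, from SYNPO2 at -3.29, while the human bars stay between -0.13 (PLN) and 0.75 (MYOCD).

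Rat leiomyoma had lower levels of contractile and epithelial transcripts than myometrium and higher levels of cell cycle, matrix and biosynthetic ones. The calls of these lists were lost with an estimated correlation between genes (lowest adjusted p = 0.186). By fry in 1 direction they passed with an adjusted p up to 1.8e-05, but so did the housekeeping list (adjusted p = 7.9e-10). Tsc2, the gene defective in this model, fell by 0.99 ± 0.10 log2 in leiomyoma, or 1.99-fold (intensity 89.8 against 190; adjusted p = 1.3e-09). The log2 signal ranged from 5.82 to 7.21 over 14 leiomyoma arrays and from 7.31 to 8.01 over 15 myometrium arrays, with no overlap. The largest rise was in Mlana, a gene known from pigment cells, at 5.32 ± 0.35 log2 or 39.8-fold (intensity 1549 against 27.1; adjusted p = 1.8e-13). The BMP family gene Gdf10 rose by 3.99 ± 0.25, Edil3 by 3.99 ± 0.19, the BMP antagonist gene Grem1 by 3.58 ± 0.32 and the retinoic acid binding protein gene Crabp1 by 3.53 ± 0.34, besides Lnx1 (3.78), Gria2 (3.76), Fam167a (3.41), Capn6 (3.33) and Prrx2 (3.29). The largest fall was in Pnoc, the prepronociceptin gene, at -4.96 ± 0.30 or 31.2-fold lower (adjusted p = 1.7e-14). Kap (-4.27), Plet1 (-4.04), A2ml1 (-3.97), Ptgis (-3.84), C3 (-3.83), Pigr (-3.80), Mmp7 (-3.74), Ccl21 (-3.42) and Synpo2 (-3.29) followed. With the epithelial marker mean as a covariate Kap was at -0.31 ± 0.66, A2ml1 at -0.58 ± 0.65, C3 at -0.33 ± 0.49 and Mmp7 at 0.92 ± 0.87, none of them called (lowest adjusted p = 0.444).

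Among 10481 rat genes 3197 were higher and 2964 lower in leiomyoma, or 58.8%, and 270 and 470 of these changed at least 2-fold. Of the called genes 51.9% were higher, which centring on array medians moved to 67.9%, and centring moved the median of all genes from 0.0152 to 0.135 log2. With the array median as a covariate 1879 genes were lower, and with the epithelial marker mean as a covariate 1924 were higher and 1649 lower.

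All 24 measured contractile genes fell in rat leiomyoma, and all 24 did so adjusted over the list alone, with a median of -1.57 (camera adjusted p = 3.3e-12; adjusted p = 0.237 with an estimated correlation). Synpo2 was at -3.29 ± 0.23, the calponin gene Cnn1 at -3.09 ± 0.38 and Myocd at -1.06 ± 0.14. Cell cycle genes rose in 23 of 28 cases and fell in 1, or 24 and 1 adjusted over the list alone, with Cdk1 at 1.67 ± 0.20, Top2a at 1.54 ± 0.26 and Mki67 at 1.06 ± 0.21 (camera adjusted p = 3.9e-05; adjusted p = 0.318 with an estimated correlation). The gene that fell was Ccnd1 (-0.42 ± 0.14), not called under median centring (adjusted p = 0.0663). Mki67 was at 0.58 ± 0.30 with the array median as a covariate (adjusted p = 0.129) and at 0.75 ± 0.35 with the epithelial marker mean (adjusted p = 0.102). The Top2a call was lost there too (1.1 ± 0.45, adjusted p = 0.0558), and both calls ended through smaller changes and wider errors. Collagen genes rose in 17 of 21 and fell in 1 (camera adjusted p = 3.9e-04; adjusted p = 0.264 with an estimated correlation), with Col8a1 at 1.42 ± 0.22, Col16a1 at 1.38 ± 0.09, Col1a1 at 1.18 ± 0.16, Col3a1 at 0.62 ± 0.09 and Col14a1 at -1.61 ± 0.20. Other matrix genes rose in 17 of 31 and fell in 4, with the versican gene Vcan at 2.82 ± 0.25, Thbs2 at 2.65 ± 0.26 and Fmod at -1.53 ± 0.25 (camera adjusted p = 0.0018; adjusted p = 0.186 with an estimated correlation). Fmod was at -0.90 ± 0.42 (adjusted p = 0.0996) and Col3a1 at 0.40 ± 0.16 (adjusted p = 0.0514) with the epithelial marker mean as a covariate, smaller and with wider errors. Collagen and matrix counts were unchanged adjusted over the list alone.

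Epithelial markers fell in 14 of 14 cases in rat leiomyoma, also adjusted over the list alone, with Mmp7 at -3.74 ± 0.78 and the adhesion molecule gene Epcam at -3.09 ± 0.35 (camera adjusted p = 1.3e-05; adjusted p = 0.264 with an estimated correlation). Endothelial markers fell in 10 of 14 and rose in 1 (camera adjusted p = 0.0078; adjusted p = 0.374 with an estimated correlation), with the claudin gene Cldn5 at -1.99 ± 0.26 and Ramp2 at 0.46 ± 0.12. Mesothelial markers fell in 4 of 5 (Wt1, -2.33 ± 0.11; camera adjusted p = 0.0283; adjusted p = 0.186 with an estimated correlation), and skeletal muscle markers in 4 of 6 (Acta1, -2.94 ± 0.51; camera adjusted p = 0.0482; adjusted p = 0.264 with an estimated correlation). Interferon response genes fell in 10 of 13, or 11 adjusted over the list alone, with Mx1 at -1.01 ± 0.12 (camera adjusted p = 0.0137; adjusted p = 0.357 with an estimated correlation). Fibroblast markers rose in 7 and fell in 4 of 11, with Pdgfrb at 1.45 ± 0.13 and Pi16 at -2.43 ± 0.26 (camera adjusted p = 0.144; adjusted p = 0.264 with an estimated correlation). Ramp2 was not called with the array median (0.28 ± 0.18, adjusted p = 0.224) or the epithelial marker mean (0.39 ± 0.20, adjusted p = 0.140) as a covariate, nor Acta1 with the array median (-1.71 ± 0.75, adjusted p = 0.0706). The skeletal muscle call was lost with a larger offset, with no filter, with array weights and without probe sets that can bind several transcripts (adjusted p from 0.0526 to 0.158). It was also lost in 3 fits chosen after seeing the data. The interferon call was lost with a filter at the 60th percentile (adjusted p = 0.0537) and with the array median as a covariate (adjusted p = 0.197). The epithelial marker mean as a covariate ended the interferon and mesothelial calls (adjusted p = 0.0706 and 0.127). Except for the interferon genes, counts were unchanged adjusted over the list alone.

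The mTOR pathway components of the rat went both ways. Of 38 members 15 rose and 10 fell, also adjusted over the list alone. These 25 calls stood against 58.8% of all rat genes called. The median of 0.10 was not past the threshold by camera (adjusted p = 0.402, or 0.424 with an estimated correlation). Fry called the list in 1 direction (adjusted p = 1.9e-05) and for changes either way (6.0e-28). It did the same for the housekeeping list (7.9e-10 and 1.0e-04). Ddit4, an inducible inhibitor of mTOR complex 1, rose by 1.16 ± 0.18, Lamtor3 by 0.84 ± 0.08, Akt1 by 0.50 ± 0.06 and Eif4ebp1 by 0.29 ± 0.09. Besides Tsc2, Pik3ca fell by 0.77 ± 0.09, Rictor by 0.46 ± 0.07, Mtor by 0.21 ± 0.05 and Rheb by 0.15 ± 0.06, and the Mtor and Rheb calls were lost under median centring (adjusted p = 0.179 and 0.708). With the array median as a covariate the calls of Eif4ebp1 (0.03 ± 0.14, adjusted p = 0.886) and Rheb (-0.20 ± 0.09, adjusted p = 0.0702) were lost. The epithelial marker mean as a covariate ended those of Ddit4, Mtor, Rheb and Eif4ebp1 (adjusted p = 0.0523, 0.0671, 0.322 and 0.434). Mtor stayed at -0.21 ± 0.09 and Rheb at -0.13 ± 0.10 with wider errors, whereas Ddit4 went to 0.75 ± 0.30 and Eif4ebp1 to 0.18 ± 0.16. Rps6kb1 was at 0.19 ± 0.08 on a probe set that can bind several transcripts and at -0.18 on another (adjusted p = 0.125). Tsc1 was at -0.01 ± 0.09 and Rptor at -0.11 ± 0.07, neither called.

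Lists of metabolic genes that mTOR complex 1 can induce were higher in rat leiomyoma. Its activity was not measured, and what raised these genes was not tested. The ATF4 amino acid and serine program rose in 15 of 21 cases and fell in 3, with Cebpb at 1.1 ± 0.15, the serine synthesis gene Phgdh at 1.08 ± 0.17 and Asns at -0.41 ± 0.11 (camera adjusted p = 5.7e-04; adjusted p = 0.186 with an estimated correlation). Sterol and fatty acid synthesis genes rose in 14 of 17 and fell in 2, with the lanosterol synthase gene Lss at 1.59 ± 0.09 and Idi1 at -1.02 ± 0.29 (camera adjusted p = 0.0019; adjusted p = 0.357 with an estimated correlation). Glycolysis and HIF targets rose in 14 of 24 and fell in 1, with Pgk1 at 0.92 ± 0.12, Tpi1 at 0.85 ± 0.10 and Pfkp at -1.64 ± 0.16 (camera adjusted p = 0.0103; adjusted p = 0.374 with an estimated correlation). Quantile normalization ended the call of the glycolysis list (adjusted p = 0.0781), and the array median as a covariate that of Asns (-0.23 ± 0.17, adjusted p = 0.277). Under the epithelial covariate Asns turned to 0.20 ± 0.13 and Idi1 to 0.10 ± 0.44, neither called (adjusted p = 0.264 and 0.884). Insulin-like growth factor genes rose in 9 and fell in 5 of 16, with Igf1 at 1.56 ± 0.23, Igfbp2 at 1.97 ± 0.32, Igf2 at -2.37 ± 0.17, Igf1r at -1.31 ± 0.14 and Insr at -0.71 ± 0.12 (camera adjusted p = 0.611). Igfbp2 was at 1.12 ± 0.53 and not called with the epithelial marker mean as a covariate (adjusted p = 0.102). All these counts were unchanged adjusted over the list alone.

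**Figure D2:**
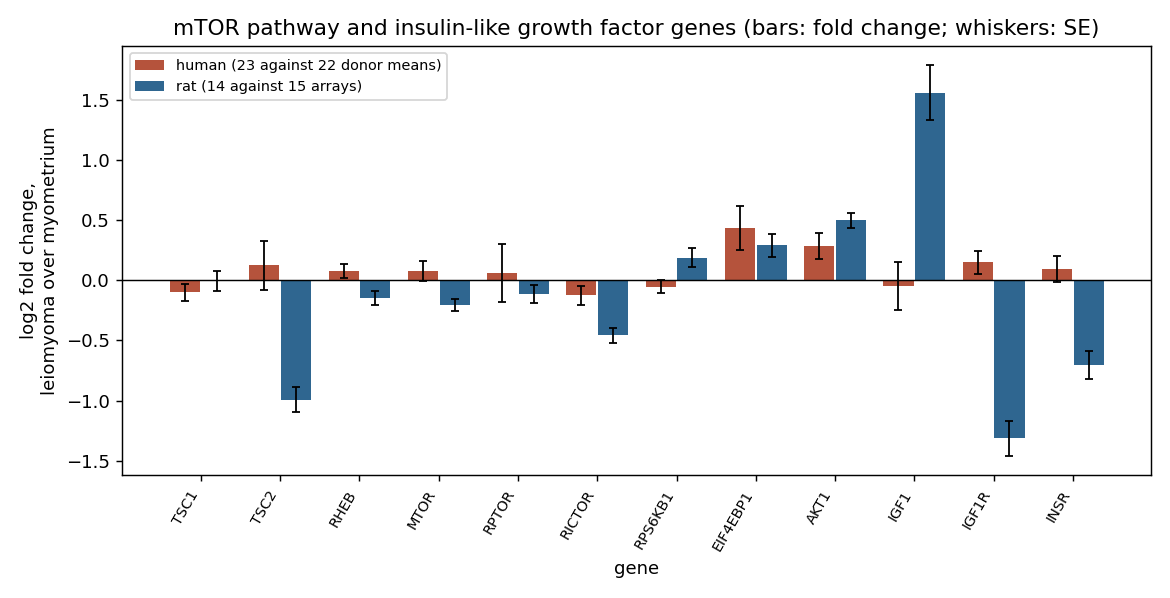
Log2 fold change of leiomyoma over myometrium (vertical axis) for mTOR pathway and insulin-like growth factor genes, with bars for the fitted change (red, human, 23 against 22 donor means; blue, rat, 14 against 15 arrays) and whiskers for the standard error. TSC2 lies at 0.12 in human and -0.99 in rat, and IGF1 at -0.05 and 1.56.

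Genes called in both species mostly moved the same way. Of 8931 matched genes 415 were higher in leiomyoma of both, against 262.9 expected for independent lists (odds ratio 2.36; Fisher's exact test, adjusted p = 1.3e-30), and 560 were lower in both against 316.1 (odds ratio 3.00; adjusted p = 3.1e-61). Fisher's test treats genes as independent, so the rat labels were also permuted 100 times, taking as many rat genes from each end of the ranking. The permutations shared a median of 265 and 327.5 genes and at most 428 and 597. The permutation p, one-sided and unadjusted, was 0.0198 and 0.0495, the latter barely under the threshold. The shared genes made up 975 of 1317 genes called in both, or 74.0%. Genes higher in both included ZMAT3, a p53 target (1.06 ± 0.12 in human and 0.93 ± 0.08 in rat), GRIA2 (3.03 ± 0.39 and 3.76 ± 0.39), CAPN6 (3.48 ± 0.45 and 3.33 ± 0.30) and the membrane metalloproteinase gene MMP14 (1.29 ± 0.18 and 1.69 ± 0.14), besides MMP11, IGSF3, PDGFC and COL5A2. Genes lower in both included SORBS2 (-1.62 ± 0.18 and -1.71 ± 0.14), ABLIM1 (-1.44 ± 0.20 and -1.66 ± 0.14), the retinaldehyde dehydrogenase gene ALDH1A1 (-2.55 ± 0.27 and -1.33 ± 0.17) and the cytokine gene IL15 (-1.22 ± 0.14 and -0.74 ± 0.10), besides SPTBN1, MYO5C, ARAP2 and KAT2B. The rat call of PDGFC was lost with the array median (0.44 ± 0.18, adjusted p = 0.0520) and the epithelial marker mean (0.40 ± 0.20, adjusted p = 0.134) as covariates, and that of ARAP2 with the latter (-0.26 ± 0.14, adjusted p = 0.144). With the donor as a random block the count higher in both was 716, and with only the first biopsy it was 238. It was 259 without probe sets that can bind several transcripts, median centring left 278 lower in both, and the epithelial covariate left 66 and 159.

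A further 342 genes were called in opposite directions, 153 higher in human and lower in rat and 189 the other way, against 235.7 and 352.6 expected. The chloride channel gene ANO1 was at 1.52 ± 0.24 in human and -1.20 ± 0.14 in rat, and POPDC2, THSD4, SLC24A3 and GOLM1 had the same pattern. CCN5 was at -2.35 ± 0.35 in human and 2.95 ± 0.30 in rat, DPT at -2.32 ± 0.29 and 1.3 ± 0.12, and MGST1, HSD11B1 and PROS1 went the same ways. Across genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.223 and Spearman rho = 0.244. Against 100 permutations of the rat labels this Pearson r was not past the threshold (two-sided permutation p = 0.109). Permuted labels keep the tissue difference in the rat arrays, so this test cannot decide on agreement by chance.

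**Figure D3:**
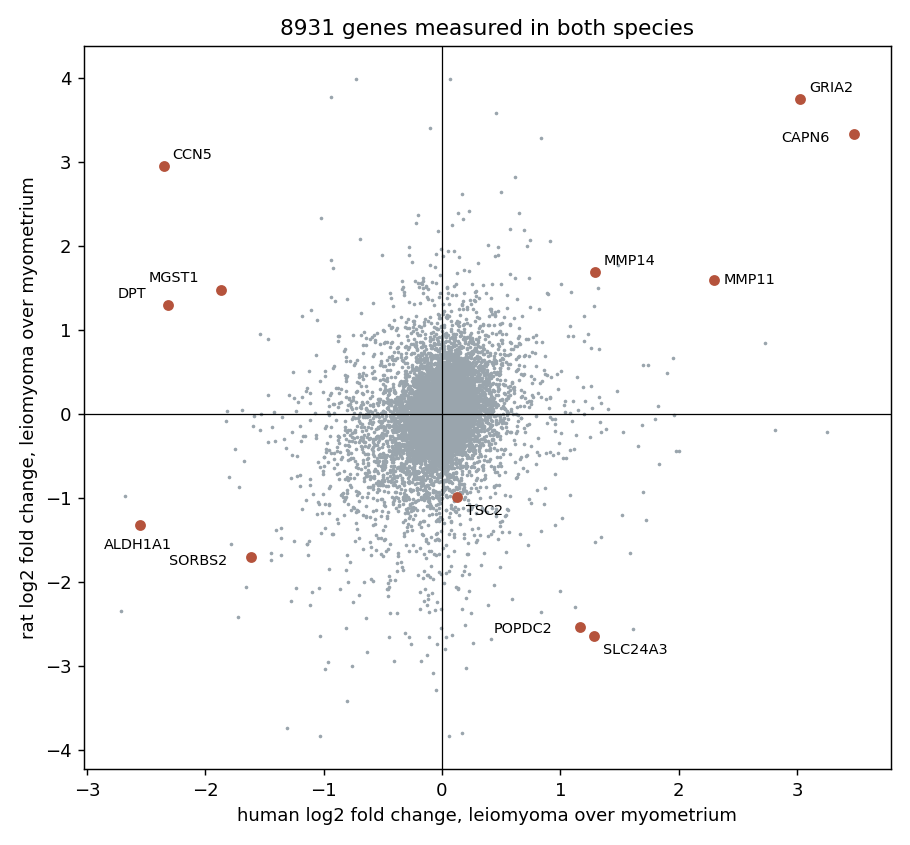
Human (horizontal axis) and rat (vertical axis) log2 fold change of leiomyoma over myometrium, with 1 point for each of the 8931 genes measured in both species and named genes marked in red. GRIA2 and CAPN6 lie far up in both species, ALDH1A1 and SORBS2 are down in both, and CCN5, DPT, MGST1, POPDC2 and SLC24A3 lie in the quadrants of opposite change.

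The change differed between the species for 3683 genes, or 41.2% (1978 with the epithelial marker mean as a covariate), with 1731 more positive in human and 1952 in rat. Platforms differ in how far they compress fold changes, and 637 of these genes were called in both species. Of 25 lists measured in both species 8 differed. The contractile list differed most, with a median difference of 1.77 log2, and all 22 members compared were more positive in human (adjusted p = 1.0e-20). The mTOR pathway components did not differ as a list (median difference -0.06, adjusted p = 0.898), although TSC2 itself did (1.12, adjusted p = 4.6e-05).

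**Figure D4:**
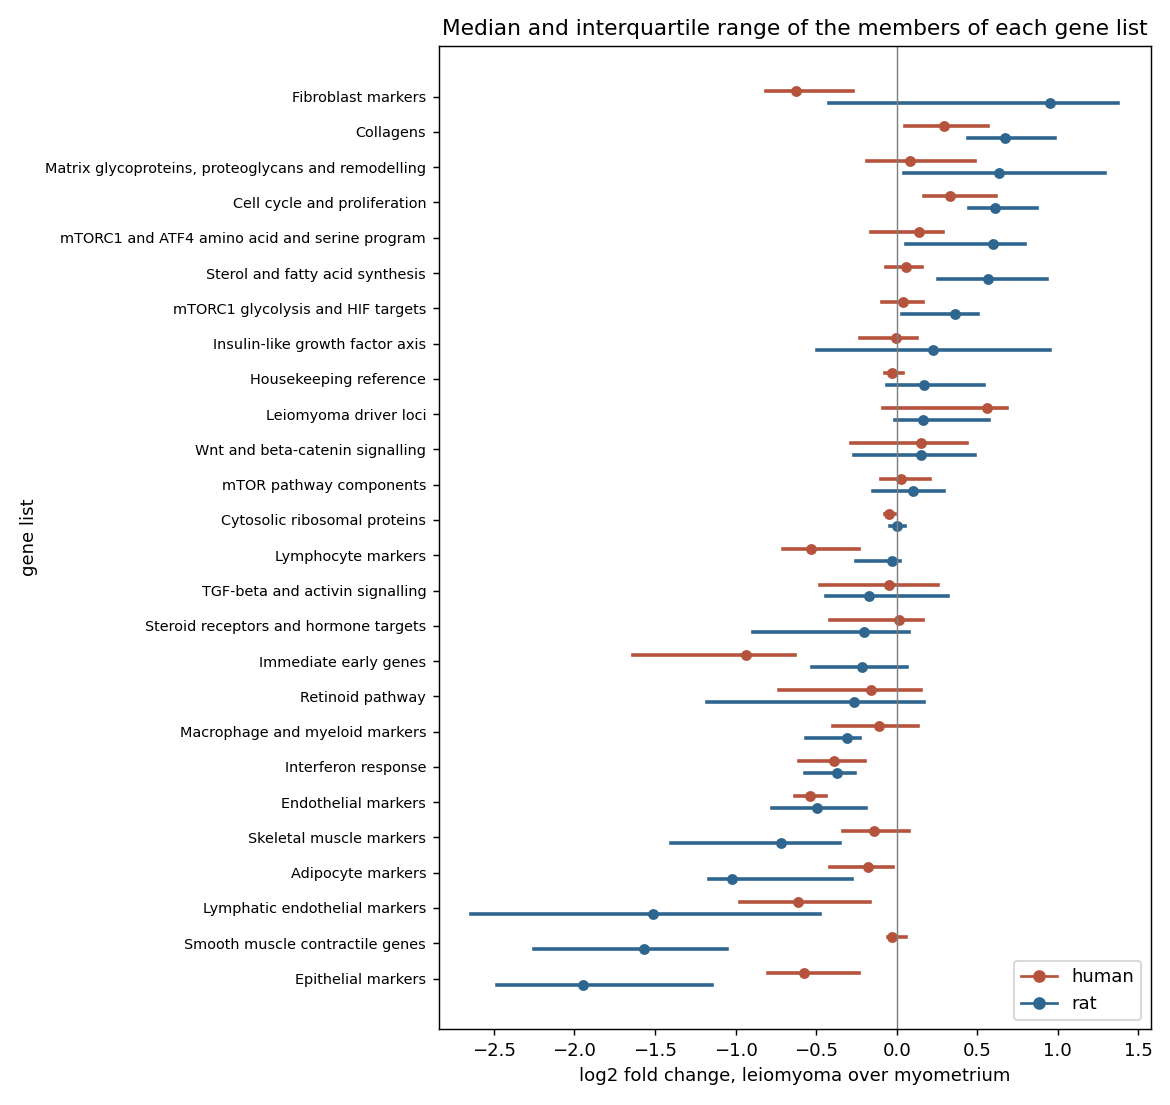
Median (point) and interquartile range (line) of the log2 fold changes of leiomyoma over myometrium (horizontal axis) over the members of each list tested in both species (vertical axis; red, human; blue, rat). The contractile median lies at -0.03 in human and -1.57 in rat, and the epithelial median at -0.58 and -1.95.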

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

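The tests of a lower smooth muscle share, of epithelium in the rat myometrium and of the chance level of the correlation and of the genes shared by direction were chosen after the results they bear on had been seen.

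The change from myometrium to leiomyoma differed between human and rat for 3683 genes by the test of the difference itself. Of 100 other splits of the samples 0 gave any such gene. Those splits removed the tissue change from both species, so they cannot tell an equal change from a different one. Platforms compress fold changes to different degrees, so a difference in size without a difference in sign carries less weight. All differences below are human minus rat on the log2 scale. Of 18 genes of the fixed set measured in both species 12 differed.

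Besides the contractile list, at a median difference of 1.77, the epithelial markers differed by 1.43 (adjusted p = 0.014), having fallen further in rat. Fibroblast markers differed by -1.52 (adjusted p = 5.2e-04), falling in human and going both ways in rat. Immediate early genes differed by -0.93 (adjusted p = 0.0038) and the matrix list by -0.40 (adjusted p = 0.0155). The mTORC1 and ATF4 program differed by -0.48 (adjusted p = 0.0038), sterol and fatty acid synthesis by -0.46 (adjusted p = 0.0108), and glycolysis and HIF targets by -0.34 (adjusted p = 0.0422). All these list comparisons used the preset correlation of 0.01 and were not repeated with an estimated one, so their p-values may be too small.

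Among mTOR pathway genes TSC2 differed by 1.12 (adjusted p = 4.6e-05), RICTOR by 0.33, MTOR by 0.29, RHEB by 0.23 and RPS6KB1 by -0.24. The RPS6KB1 difference rests on the probe set, since the rat gene was at -0.18 without probe sets that can bind several transcripts, below the human -0.05. In the growth factor axis IGF1R differed by 1.46 (adjusted p = 5.7e-10), IGF1 by -1.61 (adjusted p = 1.5e-05) and INSR by 0.80. MKI67 differed by -0.97 (adjusted p = 0.0015, although the rat call was lost with either covariate, the array median or the epithelial marker mean), COL1A1 by -0.73, COL3A1 by -0.36 and TGFB3 by 1.18 (adjusted p = 5.9e-04). The remaining adjusted p of these genes were 0.0451 or less.

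Genes that moved the same way in both species but by different amounts were IGSF3 (1.29), COL5A2 (-0.43), SPTBN1 (0.38), ALDH1A1 (-1.22), MYO5C (1.05), IL15 (-0.48) and KAT2B (-0.34). Among genes that moved in opposite directions the differences were large, with SLC24A3 at 3.93, POPDC2 at 3.71, THSD4 at 3.11, ANO1 at 2.72 and GOLM1 at 2.23. On the other side stood CCN5 at -5.30, DPT at -3.62, MGST1 at -3.35, HSD11B1 at -2.77 and PROS1 at -1.45. These opposed genes were selected for opposite changes, and those above for large shared ones, so their differences describe the selection and are not further evidence that the species differ.

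Contractile genes fell in rat leiomyoma, while in human leiomyoma 1 rose and 1 fell of 23. Scaling between arrays is argued against, since 24 of 24 rat genes fell under both quantile normalization and median centring. A ceiling on bright human probe sets is argued against only weakly. The 11 members below the list median differed by 1.71 ± 0.82 (SD) between species. These dimmer members lay at or above percentile 66.3 of the human gene levels, and the 11 brighter ones at or above percentile 99.3. The markers of the other cell types did not rise alike in the rat tumours. Endothelial markers had a median of -0.50 and epithelial markers of -1.95 while fibroblast markers had 0.95. This cannot decide on a lower share of smooth muscle, since only the cells that take its place need rise. A gain of fibroblast-like cells in place of muscle stays open, and so does a lower contractile program within the tumour cells, as a hypothesis. Differences of species, model and the site of the sampled myometrium stay open and untested.

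A larger share of genes was called in rat (58.8%) than in human (20.0%, or 24.8% with the donor as a fixed block over paired means and 31.4% as a random block over all arrays). The rat fit had fewer samples than the human one, 14 against 15 and 23 against 22, which would lower its share, and a smaller spread between the rat arrays alone is argued against. The median absolute change over matched genes was 1.92 times as large in rat (0.262 against 0.137), although the residual SD was also smaller (0.232 against 0.343). With the epithelial marker mean as a covariate the rat share was 34.1% and the human share 7.32%, which counts against epithelium as the whole cause, and the lost rat calls went with a rise of the median standard error from 0.0874 to 0.150 while the median absolute change went from 0.257 to 0.264; with the array median as a covariate the shares were 38.6% and 22.0%, at a median standard error of 0.132 and a median absolute change of 0.256 in rat. Tumours of a single animal model against tumours of many donors, and the platforms, stay open and may contribute.

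Other splits of the samples were drawn 100 times, human ones by exchanging the tissues within donors and rat ones across arrays. For the 1193 human genes higher and 1645 lower the highest other split gave 0 each, and for the 3197 and 2964 rat genes 1 each, so in each case only 1 split, the real one, was as large and chance can be excluded. Relabelled rat arrays, at the same number of rat genes, shared at most 428 and 597 genes with the human calls against the real 415 and 560. With the real one counted 2 and 5 of them were as large, under the threshold for the genes higher in both and only barely for those lower in both. These counts were one-sided and unadjusted, and some relabellings shared more genes than the real arrays, so they argue against chance only weakly. For the correlation of 0.223, counted on both sides, chance cannot be excluded. There 11 relabellings, the real one counted, were as large and the highest other gave 0.268. The main axis of variation of the rat arrays held 47.9% of the variance, and tissue explained 0.96 of that axis. Relabelling keeps this tissue difference, so an uneven draw gives fold changes along it. The correlation test therefore cannot decide, and the test of shared genes has the same limit. By camera chance cannot be excluded for the mTOR pathway components either. With the real ones counted, 45 human splits and 30 rat splits gave a camera p as small as the real 0.351 and 0.313. The lowest of the others were 0.0068 and 0.0386. These splits were not run with fry.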

How the results depend on the processing

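The covariates of array median and epithelial markers, and the fit without poorly correlating arrays, were chosen after seeing the data. Over 21 alternatives, 158 of 186 values of the main results held within 1.5 times or on the same side of the threshold and 28 moved, while 3776 of 3971 values of named genes kept direction and call, 146 lost and 13 gained a call, 28 moved without being called and 8 reversed. Of 841 list values 776 were the same, 26 lost and 19 gained a call, 19 moved and 1 reversed. The dimmest genes are limited by the signal over background, and the offset compresses their changes. The correlation between species ran from 0.151 to 0.236. By camera the mTOR pathway list passed the threshold in neither species under the alternatives that gave it a value. A minimum fold leaves no value for the correlation, the species difference or the mTOR lists, and matching by the same symbol alone gave none for the mTOR lists.

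Fewer samples or a minimum fold lowered counts by construction. With 14 against 14 donor means 379 human genes were higher and 860 lower, and 103 and 304 were shared with rat. At 2-fold or more the counts were 148 and 158 in human, 270 and 470 in rat, and 11 and 32 in both. With only the first biopsy, 693 human genes were higher and 238 higher in both. With the donor as a random replicate block over all 77 arrays 2066 human genes were higher (1192 of the 1193 among them) and 716 were higher in both, at a donor correlation of 0.230. With the donor as a fixed replicate block over paired means 1489 were higher and 2032 lower, and neither block alone changed a call of a named gene or list beyond those given with the results.

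Median centring gave 930 lower human genes and 278 lower in both, and leaving out probe sets that can bind several transcripts gave 259 higher in both with fewer genes tested. The array median as a covariate gave 1879 lower rat genes, a human mTOR median of -0.0103 (-0.0191 with the donor as a fixed block as well) and -0.24 for rat INHBA. The cause was not tested. Quantile normalization made 57.5% of the rat calls higher.

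The epithelial marker mean as a covariate gave 425 higher and 614 lower human genes, 1924 and 1649 in rat, 66 and 159 in both, 1978 differing between species and a human mTOR median of -0.0335. It left a human epithelial median of -0.0702 and reversed rat MMP7 (0.92), KRT19 (0.0459), ASNS (0.20), IDI1 (0.10) and LTBP2 (0.0192), none called. The covariate is built from the epithelial genes and follows the groups, which removes their own shift by construction and widens errors, and it ended 65 of the lost gene calls; for the other genes the cause was not tested. Rat SC5D turned to 0.15 as a mean over probe sets, and rat RPS6KB1 to -0.18 without probe sets that can bind several transcripts, since other probe sets then stood for the gene. No paired analysis was possible for rat because donor numbers are not shared between tissues, so any pairs of tissues from the same animal could not be recognized.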

Other observations

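The lists and tests of melanocytic and lysosome genes were chosen after the rise of single rat genes, Mlana and Gusb, had been seen, and the macrophage test after its values had been seen.

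Signalling lists moved in both directions in human leiomyoma, and the shift of none of those in this paragraph passed the threshold of camera in the fit given here. Fry in 1 direction called the retinoid (adjusted p = 2.6e-05), driver (0.0010) and TGF-beta lists (0.018) and none of the others. TGF-beta and activin genes rose in 3 and fell in 8 of 23 cases (camera adjusted p = 0.463), with BMP4 at -1.27 ± 0.27 and CCN2 at -1.18 ± 0.26. Wnt genes rose in 5 and fell in 3 of 20 (adjusted p = 0.456), with the Wnt inhibitor gene WIF1 at 1.90 ± 0.36. Retinoid genes rose in 2 and fell in 6 of 14 (adjusted p = 0.105), the binding protein gene CRABP2 at 1.40 ± 0.27 against ALDH1A1 and ADH1B among the largest falls. Steroid receptor and target genes rose in 2 and fell in 7 of 20 (adjusted p = 0.456), with the prolactin gene PRL at 1.99 ± 0.38, higher in 21 of 22 donors, and the receptor genes ESR1 and PGR at 0.15 ± 0.15 and 0.05 ± 0.18. Leiomyoma driver loci rose in 3 of 11 (adjusted p = 0.0685), including RAD51B at 1.42 ± 0.36, and HMGA2 was at 0.64 ± 0.27 (adjusted p = 0.083). HMGA2 was called higher under quantile normalization (adjusted p = 0.0398), median centring (0.0423) and the array median as a covariate without and with the donor as a fixed block (0.0350 and 0.0483). The driver list was called without the poorly correlating arrays (0.0302), and the retinoid list was called lower under median centring (0.0427). With the epithelial marker mean as a covariate the calls of CCN2 (-0.78 ± 0.34, adjusted p = 0.177) and RAD51B (1.35 ± 0.48, adjusted p = 0.0774) were lost. RAD51B was not called with 14 against 14 donor means either (1.16, adjusted p = 0.116). Nerve markers rose in 3 and fell in 1 of 5 (adjusted p = 0.324), macrophage markers fell in 4 of 15 (median -0.11, adjusted p = 0.322), adipocyte markers in 1 of 6 (adjusted p = 0.456), and skeletal muscle markers rose in 1 and fell in 1 of 6 (adjusted p = 0.725). The macrophage list was called lower in the single random draw of 14 against 14 donor means (median -0.38, adjusted p = 5.0e-04), with the donor as a fixed block and the array median as a covariate (-0.21, adjusted p = 0.0374) and with the epithelial marker mean as a covariate (-0.30, adjusted p = 0.0447). Insulin-like growth factor genes rose in 1 and fell in 1 of 15 (adjusted p = 0.781). By limma 0 of 49 ribosomal protein genes and 0 of 10 housekeeping genes were called, with 1 in each list at an unadjusted p under 0.05 (camera adjusted p = 0.456 and 0.966), though with only the first biopsy the ribosomal list was called lower (median -0.12, adjusted p = 0.0104). Of 4 mesothelial and 2 red blood cell markers, too few to test, 1 each fell. The fall of the hemoglobin gene HBB (-1.71 ± 0.34) was not called without probe sets that can bind several transcripts (-0.12, adjusted p = 0.806). Nor was it with the epithelial marker mean as a covariate (-1.04 ± 0.44, adjusted p = 0.153).

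In rat leiomyoma Wnt genes rose in 7 and fell in 5 of 19 cases (camera adjusted p = 0.691), with Wnt4 at 1.92 ± 0.36 and Sfrp4 at -1.24 ± 0.24, the latter against 1.02 ± 0.34 in human. TGF-beta and activin genes rose in 8 and fell in 6 of 22 (adjusted p = 0.691), retinoid genes rose in 4 and fell in 6 of 14 (adjusted p = 0.297), and steroid genes rose in 3 and fell in 7 of 18 (adjusted p = 0.144), with the estrogen-induced gene Greb1 at -1.90 ± 0.50. Immediate early genes rose in 4 and fell in 8 of 22 (adjusted p = 0.224), with Sgk1 at 1.39 ± 0.18 and Fos at -0.98 ± 0.18. With the epithelial marker mean as a covariate Greb1 (-0.67 ± 0.83, adjusted p = 0.569), Fos (-0.39 ± 0.28, adjusted p = 0.296) and Sfrp4 (-0.71 ± 0.41, adjusted p = 0.191) were not called. Driver loci rose in 3 and fell in 2 of 10 (adjusted p = 0.592). Lymphatic markers rose in 1 and fell in 4 of 5 (adjusted p = 0.0663). Lymphocyte markers fell in 3 of 7, or 1 adjusted over the list alone (adjusted p = 0.455). Macrophage markers rose in 2 and fell in 7 of 14 (adjusted p = 0.138), and adipocyte markers rose in 1 and fell in 5 of 7 (adjusted p = 0.146). The lymphatic list was called lower under median centring (adjusted p = 0.0203), with no filter (0.0309) and with the array median (0.0411) or the epithelial marker mean (0.0346) as a covariate. The macrophage list was called lower with an offset of 1 (0.0368) and with a filter at the 60th percentile (0.0334). Ribosomal protein genes rose in 1 and fell in 1 of 39 (adjusted p = 0.884). Of 3 mast cell markers 0 were called by limma, also 0 at an unadjusted p under 0.05, and 2 of 3 nerve and 1 of 3 red blood cell markers fell. The call of Hbb (-0.87 ± 0.28) was lost with the array median (-0.18 ± 0.41, adjusted p = 0.755) and the epithelial marker mean (-1.02 ± 0.49, adjusted p = 0.108) as covariates. Housekeeping genes rose in 4 and fell in 2 of 7 (adjusted p = 0.155), with Hprt1 at 0.97 ± 0.09 and Gusb, a lysosomal enzyme gene, at 0.90 ± 0.06.

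The median, the mean and the camera direction differed in sign for the human insulin-like growth factor, glycolysis, contractile and steroid lists and for the rat ribosomal protein and TGF-beta lists, none of which was called.

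A hypothesis for the rise of Mlana by 5.32 log2 in rat leiomyoma is an active MiT-TFE transcription factor program, since these factors drive both melanocytic and lysosomal genes. Whether mTOR complex 1 would raise or lower their activity here was not tested. In a list of lysosome and autophagy genes 17 of 22 rose and 1 fell in rat, with a median of 0.51 (camera adjusted p = 9.3e-06 over 29 rat lists, lost at adjusted p = 0.150 with an estimated correlation), and Gaa at 1.11 ± 0.12, Fnip2 at 0.99 ± 0.13, Atp6v1h at 0.92 ± 0.08 and Lamp1 at 0.78 ± 0.07 were chosen after their values were seen. In human 1 rose and 2 fell of 24 (adjusted p = 0.966 over 30 lists). The species differed (median -0.43, adjusted p = 1.2e-05 over the 2 added lists, tried at the preset correlation only). Scaling is argued against, because 15 of 22 rat genes rose under quantile normalization and 19 under median centring, where 34.3% and 42.4% of other genes were higher. The myeloid markers gave no sign of more macrophages, with a median of -0.31, 2 higher and 7 lower of 14. That list was not called (camera adjusted p = 0.138), so a myeloid part is not excluded. The melanocytic list decides nothing, since in rat 4 rose and 3 fell of 12 with a median of 0.14 (adjusted p = 0.412 over 29 lists), Pmel, Gpnmb and Ctsk rising, and of the factors themselves Mitf (-0.59 ± 0.20) and Tfeb (-0.26 ± 0.05) fell while Tfe3 (0.17 ± 0.09) was not called, so a wider lysosomal program may accompany Mlana while protein activity was not measured.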
